A study of Homo sapiens with 4 samples.

How the data were processed

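The series holds 4 messenger RNA libraries of MCF10A cells, an established line of non-transformed human breast epithelium with basal features. Per the labels, the cells had been co-cultured for 24 h with small extracellular vesicles (sEV), membrane particles that cells shed, from MCF7, an estrogen-receptor-positive breast cancer line. The vesicle donors had been kept under normoxia for 2 libraries (normoxic sEV) and under hypoxia for the other 2 (hypoxic sEV). The condition tag of each sample gave its group, and the labels gave the replicate numbers 1 and 2 in each group. No library without vesicles is among the samples analysed here. Parts of the sample titles and descriptions speak of untreated lymphoblastoid lines, with a different origin for each vesicle group and so along the comparison made here, against the cell type tag, the source name, the protocol and the series design, which all name MCF10A. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

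Per the labels' protocols, the libraries were made from total RNA with a QuantSeq 3' kit, which reads the end of each polyadenylated transcript, so a count does not scale with transcript length. The deposited file gives expected counts per Ensembl gene ID, all whole numbers, with 1 column per library. Per the submitters' processing notes, hg19, Bowtie2, RSEM 1.2.13 and DESeq2 were used; the notes give no role or order, and the annotation, the strand setting and the rounding are not given in the sources used here. Columns were matched to samples by the start of the sample titles, and no column was left over. The table has 57736 rows with no ID repeated, of which 39501 (68.4%) were paired with a symbol through a table of gene names. Gene types were taken from GENCODE release 29. That release is on another build than the one in the processing notes, so no coordinate is reported. No row carries the ID of any of the 37 genes of the mitochondrial genome in GENCODE 29, rRNA and tRNA genes included, and those genes were not analysed here.

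The total count was 24528368 and 19137193 in normoxic sEV replicates 1 and 2, and 24529654 and 19031972 in hypoxic sEV replicates 1 and 2. Without molecular identifiers, limits from counts cover counting error only.

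The comparison of hypoxic with normoxic sEV used edgeR 4.0.16 with the quasi-likelihood F test, TMM scaling and the filterByExpr filter on all 4 libraries, without covariates, with Benjamini-Hochberg adjustment over all rows tested and a threshold of 0.05, two-sided. Standard errors of log2 fold changes were derived from the F statistic. Before the data were examined, 34 gene lists were fixed and each list with at least 5 tested rows was tested with camera in limma 3.58.1, a competitive set test, at a preset correlation of 0.01. Also fixed were 13 genes to be named whatever their result, and a rule for naming other genes by fold change among those past the threshold. Because fewer than 5 rows passed in either direction, the rule filled up to 5 rows per direction with the lowest unadjusted p among rows whose groups did not overlap and whose mean count in the higher group was at least 50. As the counts did not behave as those of the genes beside them, only 2 of these rows per direction are given, by ID and without a gene name, and the examples per list that the rule allows were left out.

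Agreement between IDs and counts was examined by ranking the summed count of each row among the 100 rows on each side of it in the table. For a set of genes the mean of these percentiles was compared with 10000 random draws in which each row was replaced by one within the same distance (two-sided permutation test, Benjamini-Hochberg adjustment over all sets). The abundant set joined the fixed lists of ribosomal proteins, nuclear-encoded respiratory chain subunits and glycolytic enzymes. The silent set held olfactory and taste receptors, keratin-associated proteins and beta-defensins, families that few tissues express. These sets and this test were chosen after the counts had been seen. Both the edgeR fit and the percentile measure were tried on simulated data. With 200 rows of at least 10 CPM (counts scaled to a common library total) changed by known folds among the rows of this comparison, of which 13662 were tested, edgeR recovered 91.0% of 100 rows changed 2-fold and 100.0% of 100 changed 4-fold, and 4.02% of its 199 calls were false. The simulated counts varied only by the fitted trend of variability over abundance, without scatter of rows around it and without an effect of replicate number. This recovery is therefore no measure of power in the real libraries. With the 167 rows of the abundant set given the count at percentile 95 of their neighbours, the percentile measure returned a mean of 94.0. That outcome was set by the planted counts, so it checks only the calculation. The permutation test was not run on them, and where these genes rank under correct IDs was not examined.

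Alternatives were other scalings (RLE and upper-quartile), no filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn and, for the lists, an estimated correlation, ranks, RLE scaling and no filter. Thinning of all libraries to the smallest total was added after the data had been seen. Analyses were run in R 4.3.3 and Python 3.11.15.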

Results

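Gene expression was measured by 3' end sequencing in 4 libraries of cells that most labels name as MCF10A mammary epithelium. Per these labels, the cells had spent 24 h with small extracellular vesicles from MCF7 breast cancer cells. The vesicles came from normoxic donors for 2 libraries and from hypoxic donors for the other 2. Library totals ran from 19031972 to 24529654 counts, and between 17082 and 18522 of the 57736 rows were above 0 in a library. The most abundant row took between 1.52% and 1.71% of each library. The chi-square per degree of freedom between libraries over the 10756 rows above 50 counts in every library was 12.7 at the least. No pair of libraries therefore agreed within sampling noise, and all 4 were counted. Before the vesicle conditions were compared, the counts beside genes of known behaviour were read as a check of the cells and of the labels.

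Several genes that every human cell uses had almost no counts. GAPDH, a glycolytic enzyme, had 1 count in the 4 libraries together, out of 87227187 counts in all. ACTG1, a cytoplasmic actin, likewise had 1 count. EEF1A1, the translation elongation factor, had 67 counts, RPLP0 had 24 and RPL3 had 74, the last 2 being ribosomal proteins. ACTB, the other cytoplasmic actin, had 12413 counts.

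Among genes of the breast epithelium the counts were mixed. CDH1, the adhesion protein E-cadherin, had 29168 counts (334 CPM) and VIM, the intermediate filament protein vimentin, had 29413 (337 CPM), at percentiles 91.5 and 91.0 among the rows around them. KRT5, a keratin of basal epithelium, had 0 counts in every library, which allows up to 3 counts in all, or 0.0344 CPM. KRT14, its partner, had 20 and 33 counts in the normoxic sEV libraries and 41 and 33 in the hypoxic sEV libraries. KRT18, a keratin of simple epithelium, had 1 count in all. CD19 and MS4A1, surface proteins of B cells, had 3184 and 3413 counts, and ALB, serum albumin made by the liver, had 3763, more than the 3 keratins and fewer than CDH1 and VIM. The row of CFTR, an epithelial chloride channel, had 276856 and 242629 counts in the normoxic sEV libraries and 326063 and 242205 in the hypoxic sEV libraries. The row of TAAR8, a receptor of the olfactory trace amine family, had 436088 counts in the 4 libraries. ACTB, ACTG1, EEF1A1, CD19, MS4A1, ALB, CFTR and TAAR8 were picked after their values had been seen. CDH1, VIM and KRT5 were fixed by name beforehand. GAPDH, RPLP0, RPL3, KRT14 and KRT18 belong to lists fixed beforehand, but the choice of these members was not fixed. The median total was 140 counts over the ribosomal protein rows and 376 over the glycolytic rows, so GAPDH, RPLP0 and RPL3 lie below their lists.

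As groups, abundant and silent genes both ranked near the middle of the rows around them. The 167 rows of ribosomal proteins, respiratory chain subunits and glycolytic enzymes that precede the last row with a count had a median of 149 counts over the 4 libraries and ranked at a mean percentile of 45.2 among their neighbours. Random rows gave 45.9 to 54.4 (permutation p = 0.0254, adjusted p = 0.527 over all sets). The 430 rows of olfactory and taste receptors, keratin-associated proteins and beta-defensins had a median of 92 counts and a mean percentile of 50.4 (random range 47.6 to 52.7, permutation p = 0.857, adjusted p = 0.959). Ribosomal proteins alone stood at 43.4, basal epithelial genes at 48.5, luminal estrogen-receptor genes at 51.5 and B-lymphoid genes at 49.3. None of the 35 sets examined passed the adjusted threshold; 3 had an unadjusted permutation p under 0.05, each with a mean percentile below 50, and the highest mean percentile of any set was 59.0, for endoplasmic reticulum stress genes.

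**Figure D1:**
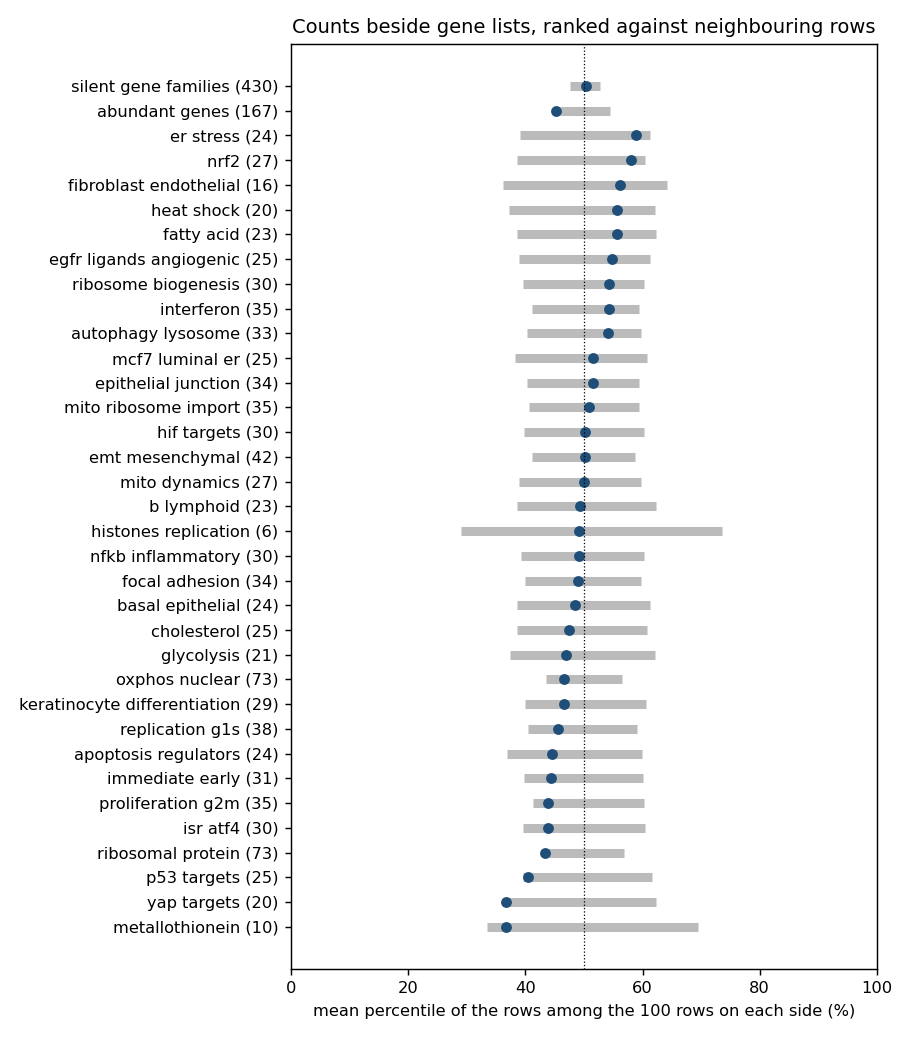
Mean percentile (x axis, %) of the counts beside each gene set among the 100 table rows on each side, with the number of rows in parentheses; dots are the observed means, grey bars the central 95% of 10000 draws of random neighbouring rows, and the dotted line marks 50. Abundant genes (45.2) and silent gene families (50.4) both lie near 50.

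The summed counts beside cell type lists were highest for the B-lymphoid and luminal estrogen-receptor lists of 25 rows each, and lowest for the basal epithelial list of 24 rows. As the counts did not behave as those of the genes beside them, these sums are not read as levels of the markers. The basal epithelial list held 574 ± 14.2 CPM (SD, n = 2) with normoxic sEV and 589 ± 22.2 (SD, n = 2) with hypoxic sEV. The luminal estrogen-receptor list, genes of the vesicle donor type, held 1107 ± 91.1 and 1101 ± 11.9, the B-lymphoid list 1173 ± 13.6 and 1251 ± 12.7, and the fibroblast and endothelial list 807 ± 30.5 and 804 ± 2.93, in the same order and each with n = 2.

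The counts followed the position of the row in the table, whose IDs ascend. Row 23816 was the last with a count. The 33920 rows after it (58.8%) were at 0 in every library, among them 6303 long intergenic RNA genes, 4916 antisense RNA genes and 1490 protein-coding genes. From row 17183 to row 21216 no row was at 0, a run of 4034 rows that included 605 small nuclear RNA genes and 76 microRNA genes. The longest run in 100 shuffles of the rows up to the last with a count was 128 rows. The shuffles spread the rows without counts evenly, which correct IDs need not do. The length of the run therefore does not decide whether the IDs are right. Up to that row, protein-coding genes had a mean percentile of 50.04 among their neighbours and small nuclear RNA genes 51.0. Their median totals were 306 and 11 counts, not matched for position. Protein-coding rows were 17760 of the 23816 rows ranked, so their mean percentile stays near 50 whether or not the IDs are right. Small nuclear RNA rows were ranked partly among other small RNA rows, as 605 of 994 lay in the run of 4034 rows. The counts along the rows were alike in all 4 columns. Over the 10756 rows above 50 counts in every library, the Pearson correlation of log2 counts was between 0.983 and 0.990 for every pair. Rows are not independent replicates. Libraries of the same cells with correct IDs can give such values too, so they do not bear on the IDs. For these reasons, no change is attributed to a named gene in what follows. The protein-coding percentile, the comparison with shuffles and the correlation between libraries are not among the reasons. Changes are given per row of the table, with a symbol only to say which row is meant.

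**Figure D2:**
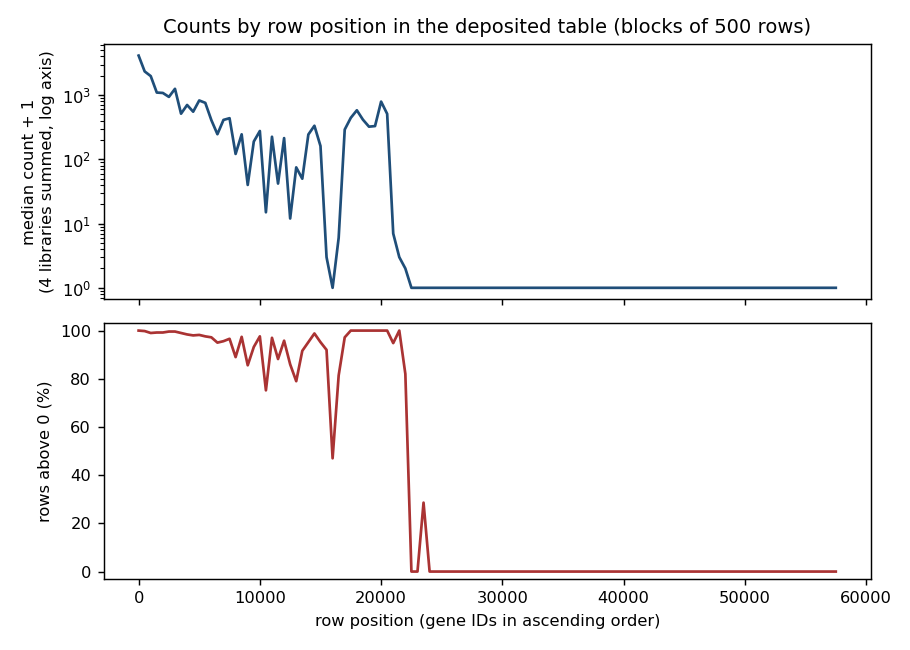
Counts by row position (x axis), in blocks of 500 rows of the deposited table with IDs in ascending order: the upper panel gives the median count over the 4 libraries summed, plus 1, on a log axis, and the lower panel the percentage of rows above 0. The rows after row 23816 are all at 0, as are the blocks that begin at rows 22501 and 23001.

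Whether vesicles from hypoxic donors changed expression in the recipient cells relative to vesicles from normoxic donors was the question of the design. No row differed between the conditions past an adjusted p of 0.05 among the 13955 rows tested (edgeR quasi-likelihood test; lowest adjusted p = 0.959). At an unadjusted p under 0.05 there were 544 rows, or 3.90% of those tested. limma-voom also called 0 rows, and DESeq2 called 14. Without the low-count filter edgeR called 67 rows, 52 higher and 15 lower with hypoxic sEV, of which 13 lay outside the rows tested with the filter. None of these fits had a term for the replicate number. With such a term the count was above 0, as given with the alternatives below. The groups did not overlap in 33.2% of rows, where 2 against 2 libraries give 1 in 3 by chance. The median size of the log2 fold change was 0.15. The median standard error was 0.18 over all rows tested and 0.12 over rows with a mean above 1000 counts. The biological coefficient of variation was 0.182.

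Among rows with at least a mean of 50 counts in the higher group, those with the lowest unadjusted p were the following, none past the adjusted threshold. The row ENSG00000024526 had 0 and 3 counts with normoxic sEV against 116 and 156 with hypoxic sEV (adjusted p = 0.959, edgeR). The row ENSG00000003989 had 623 and 512 against 1080 and 847 counts, a log2 fold change of 0.80 ± 0.13 (SE; adjusted p = 0.999). In the other direction, the row ENSG00000110911 had 188 and 64 counts with normoxic sEV against 4 and 0 with hypoxic sEV (adjusted p = 0.999). The row ENSG00000073060 had 357 and 275 against 195 and 126 counts, a log2 fold change of -0.95 ± 0.20 (SE; adjusted p = 0.999). Each of these 4 rows passed the threshold without the low-count filter, and all but the last also with DESeq2. As the rows were picked by p-value from these same libraries, this is no independent evidence of a change.

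**Figure D3:**
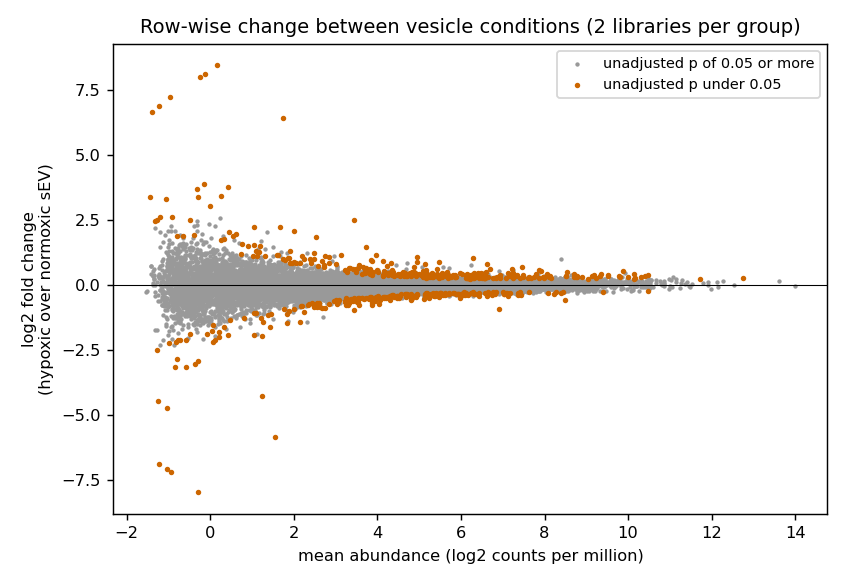
Log2 fold change of hypoxic over normoxic sEV (y axis) against mean abundance in log2 CPM (x axis) for the 13955 rows tested, 2 libraries per group, 1 point per row. The 544 rows at an unadjusted p under 0.05 are in orange; none passed the adjusted threshold.

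The gene lists fixed for this comparison were tested on the rows that carry their IDs, with the same limit on the names. If the IDs do not belong to the counts, each list is an arbitrary set of rows. The results below then say nothing about the pathways named. None of the 32 lists with at least 5 tested rows passed (camera, 0 lists at an unadjusted p under 0.05, lowest adjusted p = 0.882; lowest adjusted p = 0.978 with an estimated correlation). No row of hypoxia-inducible genes passed among 19 tested, and their median log2 fold change was -0.012. The count was 0 of 16 for mitochondrial fission, fusion and transport genes (median 0.0013), 0 of 41 for nuclear-encoded respiratory chain subunits (median -0.027) and 0 of 15 for glycolytic enzymes (median 0.13). It was 0 of 26 for mesenchymal genes (median -0.013), 0 of 25 for epithelial junction genes (median -0.0050), 0 of 21 for NF-kB-induced inflammatory genes (median -0.096) and 0 of 18 for basal epithelial genes (median 0.12). Adjusted over the list alone, 1 row passed in all lists, the row of E2F2 in the DNA replication list (log2 fold change 0.93 ± 0.18 SE; adjusted p = 0.0215 over the list alone and 0.999 over all rows, edgeR). Each list was adjusted on its own at 0.05, so 1 passing row over so many lists is no more than chance would give.

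Of the 13 genes fixed by name, the rows of KRT5 and MFN1, a mitochondrial fusion protein, had too few counts to be tested. None of the other 11 passed, with log2 fold changes from -0.50 to 0.25 and a lowest unadjusted p of 0.0192 (edgeR). The row of HIF1A, the oxygen-regulated transcription factor, had 210 and 155 counts with normoxic sEV and 195 and 194 with hypoxic sEV. The row of DNM1L, the mitochondrial fission GTPase, had 1077 and 782 against 980 and 765 counts.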

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

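The count of changed rows between the vesicle conditions was 0 with RLE or upper-quartile scaling, a mean of at least 50 counts, limma-voom, and thinning to the smallest library total, the last chosen after the data had been seen. It rose to 67 rows without the low-count filter, of which 13 lay outside the rows tested with it and 16 had 1 group at 0 throughout, to 14 rows with DESeq2, and to 50 rows with the replicate number as a block (43 higher and 7 lower with hypoxic sEV). All 14 DESeq2 rows were among the 50 of the block and among the 67 without the filter; the cause of these differences was not tested. Leaving out each library in turn gave 0 to 12 rows, the highest without normoxic sEV replicate 2; the arm left with 1 library is then assumed to vary like the other. With the replicate number as a block, 1426 rows were at an unadjusted p under 0.05 (edgeR), against 544 in the main fit. The labels do not say that a replicate number marks a shared batch. Same-numbered libraries deviated together from their group means, with a correlation of 0.367 across rows. With the condition as a covariate, 558 rows differed between the numbers (edgeR). With 2 numbers, these values are only a hint of a shared batch. The replicate block changed no list test, but with it each of the 4 rows given by ID passed the threshold. The lists stayed at 0 calls in all 9 alternatives, with 0 to 3 at an unadjusted p under 0.05. The marker list levels moved by less than their spread with CPM over filtered rows; leaving out 1 of 2 libraries is no check of these means, since it moves them by a fixed part of the SD. Of 164 alternatives for the 4 rows given by ID and the 11 fixed genes, 13 passed the threshold, each for a row given by ID, and 7 turned the direction of a change that was never past it. With limma-voom the row of FN1 was at -0.039. Without each library in turn, the log2 fold change ran from -0.44 to 0.46 for the row of FN1, from -0.17 to 0.25 for CDH1, from -0.025 to 0.32 for HIF1A and from -0.099 to 0.017 for DNM1L. Depth limits rows with few counts most: the fold of a row with a group near 0 depends on the prior count.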

Other observations

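All tests in this part were chosen after the results had been seen.

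The counts beside the gene IDs are the pattern most worth following up. A candidate explanation is that the ID column is out of step with the counts, for instance sorted without them: the abundant genes ranked at a mean percentile of 45.23 among their neighbouring rows, where any row would stand near 50, although this lies just under the random range of 45.9 to 54.4 before adjustment. The tables argue against IDs that are right from row 1 to 5954, from 5955 to 11908 or from 11909 to 17862, since the area under the curve for abundant over silent genes was 0.314 (95% interval 0.201 to 0.442), 0.476 and 0.486 there, with an upper bound of at most 0.6071; the first interval lies below 0.5, with 13 silent rows, which IDs wholly out of step do not predict, and the rows after 17862 held too few abundant genes to be tested. They argue against correctly named B-lymphoid libraries, with rows of B-lymphoid genes at 49.28. If the IDs are out of step, this value cannot say which cells were sequenced, so the cell type was not checked by these counts. Opposite-strand counting beside correct IDs is less well tested. The 181 antisense RNA genes up to the last row with a count stood at a mean percentile of 49.1 (random range 46.0 to 54.0), and the 4916 after it were at 0. Reads of 3' ends reach an antisense gene only where it covers the end of a coding gene, and how many do was not examined. Whether and how the IDs and counts came apart and which strand was counted stay open, and the order of the rows was not used to assign other names.

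The libraries resembled each other by replicate number more than by vesicle condition. Splitting the 4 libraries by number called 63 rows, against 0 for the vesicle condition and 0 for the crossed split, and 558 rows differed between numbers with the condition as a covariate (edgeR; 1632, 544 and 160 rows at an unadjusted p under 0.05 in the 3 splits, in that order). Depth does not account for it, as 73 rows were called by number after all libraries had been thinned to the smallest total. A batch shared by each number (correlation of deviations 0.367) and exchanged labels of 1 library in each group (63 rows by number) cannot be told apart, because both predict this split. No marker gene was used to identify a condition, as the counts did not behave as those of the genes beside them.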
